A study of Mus musculus with 8 samples.

How the data were processed

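RNA sequencing values were analysed for mouse bone marrow-derived macrophages from C57BL/6 mice, cultured with M-CSF at 30 ng/ml, in 8 libraries. A short hairpin labelled NCsh or TMBIM6sh was combined with no RANKL or with RANKL at 100 ng/ml for 24 h, with 2 libraries in each of the 4 groups. All samples carry the same treatment text, so the groups without RANKL were taken from the sample titles. NCsh is not spelled out in the labels, and only 1 hairpin is named on each side, so loss of Tmbim6 and any other effect of a hairpin are confounded.

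The deposited table holds RPKM values that the authors made with HOMER's analyzeRepeats in the mm10 genome with RefSeq gene models, per the file header: tags over exons on both strands were counted, isoforms were condensed to 1 entry per gene, and counts were divided by exon length and by the tags of the library. The column heads say FPKM while the command in the header asks for RPKM, and the values are read as RPKM. The submitters' notes also name HISAT2 and DESeq2, without versions. The table lists 24940 genes, 20777 of them protein-coding and 3683 noncoding, and 410 mapped to more than 1 place. The values rise in steps of 1 tag, and these steps gave the tags per gene and library. Of 6066 to 6453 values checked per library 100% were whole within 0.1 tags. The depth was 25475000 to 28595000 tags per library, rounded. A count of 0 leaves room for up to 3 tags.

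The values were used as log2(RPKM + 1), with no further scaling. Genes were kept at RPKM of at least 1 in at least 2 libraries, which left 11040. limma 3.58.1 in R 4.3.3 fitted 1 mean per group with a shared spread (4 residual degrees of freedom, 5.54 prior degrees of freedom) and an intensity trend. P-values were adjusted with the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. The 5 comparisons were RANKL in NCsh libraries, RANKL in TMBIM6sh libraries, TMBIM6sh minus NCsh without and with RANKL, and the interaction. With 2 libraries against 2 the smallest two-sided permutation p is 0.333, so no permutation test could pass. Between duplicates the correlation of log2 values was 0.993 to 0.995 across genes, and the median absolute log2 difference 0.0742 to 0.115.

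The design, the filter, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The 27 lists cover osteoclast effectors, osteoclast transcription factors, repressors of osteoclast differentiation, RANK and costimulatory signalling, NRF2 targets, NADPH oxidase, the unfolded protein response, the integrated stress response, calcium handling, the TMBIM and BCL-2 families, autophagy, V-ATPase, lysosomal genes, interferon-stimulated genes, cytokines, cell division, p53 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, and markers of macrophages, dendritic cells, neutrophils, stromal cells, lymphocytes, and erythroid, mast and basophil cells. The 24 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. The test was repeated with an estimated correlation, and p-values were adjusted over the lists of a comparison. With an estimated correlation camera works with at most the 4 residual degrees of freedom, which makes it hard for any list to pass. The lists were also tested with fry, which asks whether members shift together, without setting them against other genes. List p-values below are from camera unless fry is named. Members called when adjusted over the list alone are counted beside those called over all genes. Of 120 list tests 41 had a median, mean and test direction that differ in sign, and 0 of the 24 called ones did. The rule for named genes takes Tmbim6, 12 osteoclast genes, the 8 largest rises and 8 largest falls per comparison (adjusted p under 0.05, mean of at least 5 RPKM in the higher group, both libraries of one group above both of the other), up to 4 members per list with the smallest p, and, where fewer than 5 genes pass in a direction, the 5 with the smallest p. Some genes that the rule names are not reported here.

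The fit was tested on simulated data, tags drawn for these genes with known changes in the comparison of hairpins with RANKL. It recovered 74.6% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 97.0% of 66 changed 4-fold. Of 186 calls 10 were false (5.38%), and 6 genes were called in a contrast with no change. The simulation changed 200 genes in 1 group and drew the noise of each gene and library separately. Its share of false calls therefore leaves out shifts shared by many genes of a library. For each of 16176 words of 7 bases, genes with and without the word in the 3' UTR were compared after adjusting for 3' UTR length and GC content. The highest values were set against 200 permutations of the gene labels. The ranks and z values of the words are thus adjusted, while shares of carriers and medians by word are not. A longer 3' UTR has more room for any word. Of the tested genes 92.9% had a 3' UTR of at least 50 bases and were searched. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

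Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, the replicate number as a block, no intensity trend, only the 4 libraries of a comparison, and leaving out each library in turn, where the lone library left in its group is assumed to vary like the other groups. Voom on the recovered tags and scaling without Rn45s and Lars2 were chosen after seeing the data. A test on raw counts was set out for a table of counts and was not run, since the table holds RPKM.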

Results

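RNA was sequenced from mouse bone marrow-derived macrophages of C57BL/6 mice, precursor cells that can become bone-resorbing osteoclasts. The cells were kept in M-CSF at 30 ng/ml, the growth factor of this lineage, and carried a short hairpin RNA, labelled NCsh or TMBIM6sh. RANKL, the cytokine that drives osteoclast formation, was given at 100 ng/ml for 24 h or left out, which made 4 groups of 2 libraries each. The series title is about loss of TMBIM6, bone loss and osteoclast formation, so the comparisons below ask how RANKL changes these macrophages and how the libraries with the TMBIM6 hairpin differ. Each of the 8 libraries held 25475000 to 28595000 tags, of which 83.5% to 86.4% fell in gene exons. Between 15103 and 15396 genes had a value above 0 per library. Of the tags in gene exons, ribosomal RNA precursor (Rn45s) took 6.67% to 8.22% and the 10 most abundant genes together took 16.0% to 19.1%. The p-values below measure only the spread between these libraries, since the labels do not say whether the duplicates came from separate animals or cultures.

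Tmbim6, a calcium-channel-like membrane protein of the endoplasmic reticulum that protects against cell death, lies on chromosome 15 at 99392947 to 99410049 (mm10, plus strand). Its level was 332 ± 2.61 RPKM (SD, n = 2) in NCsh libraries without RANKL and 11.4 ± 0.395 RPKM (SD, n = 2) in TMBIM6sh libraries without RANKL. With RANKL the levels were 315 ± 8.48 RPKM (SD, n = 2) and 10.2 ± 0.305 RPKM (SD, n = 2). In the 4 TMBIM6sh libraries Tmbim6 thus stood at 3.18% to 3.53% of the NCsh mean in the same RANKL state, from 612 to 793 tags per library. The log2 difference was -4.74 without RANKL (SE 0.0574, adjusted p = 6.52e-11) and -4.81 with RANKL (SE 0.0574, adjusted p = 5.68e-11). RANKL itself did not move Tmbim6 past the threshold, with a log2 value of -0.08 in NCsh libraries (adjusted p = 0.419) and -0.15 in TMBIM6sh libraries (adjusted p = 0.126).

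**Figure D1:**
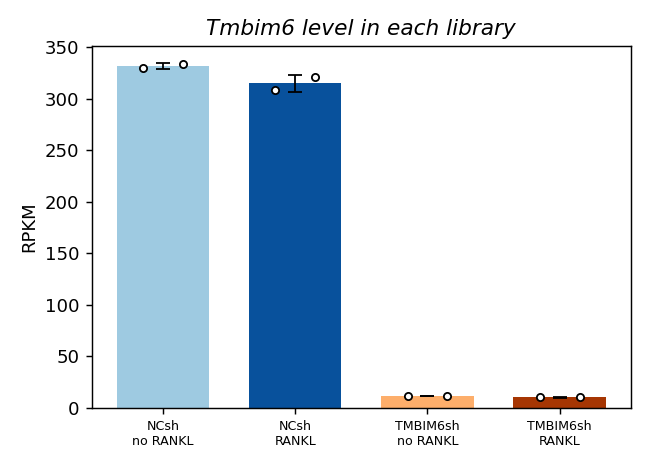
Tmbim6 level in RPKM (y axis, linear from 0) in the 4 groups; bars are means, lines the SD, and open circles the 2 libraries of each group. The NCsh libraries lie between 308.9 and 333.7 RPKM and the TMBIM6sh libraries between 10.0 and 11.7 RPKM.

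In NCsh libraries RANKL raised the cell division list (adjusted p = 0.0262 with an estimated correlation), and macrophage markers were lower as a list with the preset correlation but not with an estimated one (adjusted p = 0.734). Traf1, an adaptor of tumour necrosis factor receptors on chromosome 2 at 34941750 to 34961772, rose from 2.02 ± 0.0382 to 22.6 ± 0.146 RPKM (SD, n = 2, log2 2.97, SE 0.0795, adjusted p = 1.27e-07). Nfkb2, a precursor of the noncanonical NF-kappaB subunit, rose from 19.9 ± 0.321 to 63.6 ± 1.12 RPKM (SD, n = 2, log2 1.63, adjusted p = 7.76e-07). C3, the central component of complement, rose from 9.61 ± 0.643 to 44.9 ± 1.69 RPKM (SD, n = 2, log2 2.11, adjusted p = 5.55e-07). The other large rises were Htra1, a secreted serine protease (log2 2.35), Gpr132, a G protein-coupled receptor (2.21), the chemokine Cxcl10 (1.82), Il2rg, a shared cytokine receptor chain (1.77), and Birc3, an inhibitor of apoptosis (1.51). Here and below the largest changes are ranked on the log2(RPKM + 1) scale, which shrinks genes near 0, among genes with a mean of at least 5 RPKM in the higher group. By the ratio of means Htra1 (12.5) came before Traf1 (11.2). The largest falls were those of the chemokine Ccl7 (log2 -1.18), Ctla2b (-1.18), the ribonucleases Ang (-1.14) and Rnase4 (-1.07), whose annotated regions on chromosome 14 share the start 51091077, the D-type cyclin Ccnd2 (-1.09), the immunoglobulin receptor Fcgr1 (-1.02), H2-Q2 (-0.98) and Id1, an inhibitor of DNA-binding transcription factors (-0.97).

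Among the genes that mark osteoclasts, the picture at 24 h in NCsh libraries was mixed. Mmp9, a matrix-degrading protease on chromosome 2 at 164948219 to 164955850, rose from 12.7 ± 0.00354 to 30.2 ± 0.684 RPKM (SD, n = 2, log2 1.18, SE 0.0596, adjusted p = 8.28e-06). Src, a kinase needed for bone resorption, rose by 0.67 on the log2 scale (adjusted p = 0.00116). Nfatc1, the master transcription factor of osteoclast formation, had 6.24 ± 0.514 RPKM without and 6.58 ± 0.484 RPKM with RANKL (SD, n = 2, adjusted p = 0.666). Acp5, which encodes tartrate-resistant acid phosphatase, had 60.9 ± 5.34 and 60.0 ± 5.74 RPKM (SD, n = 2, adjusted p = 0.907). Dcstamp, a cell fusion protein, had 1.18 and 0.745 RPKM (adjusted p = 0.439). Ctsk, the collagen-cleaving cathepsin of osteoclasts, stayed at or below 0.075 RPKM in every library, and Calcr, Oscar, Ocstamp and Itgb3 reached at most 0.011, 0.04, 0.395 and 0.956 RPKM, so none of these 5 was tested. Of the 13 tested osteoclast effectors 2 rose and 1 fell, both over all genes and adjusted over the list alone. The list did not pass with camera (adjusted p = 0.984, median log2 0.01, mean 0.11, while the test pointed down). With fry it passed (adjusted p = 0.0343). The gene that fell was Atp6v0d2, a proton pump subunit used in cell fusion, from 14.9 ± 0.041 to 12.2 ± 0.0686 RPKM (SD, n = 2, adjusted p = 0.0309). That call ended in the fit of its own 4 libraries (adjusted p = 0.0663) and whenever a library other than TMBIM6sh with RANKL was left out (adjusted p = 0.0508 to 0.131).

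The transcription factors of osteoclast formation rose as a list in NCsh libraries, with 6 of 18 members higher and 0 lower, also 6 when adjusted over the list alone (adjusted p = 0.0264). That call was lost with an estimated correlation (adjusted p = 0.734), without NCsh library 2 of the group without RANKL (adjusted p = 0.074) and without NCsh RANKL library 1 (adjusted p = 0.0597). Besides Nfkb2 the members with the smallest p were Myc (log2 1.09), Jdp2 (1.06) and Fos (0.72), parts of the early transcriptional response. Repressors of osteoclast differentiation went both ways, 5 higher and 4 lower of 15 (6 and 4 adjusted over the list alone, adjusted p = 0.423). Irf8 fell from 52.4 ± 0.804 to 35.9 ± 0.122 RPKM (SD, n = 2, log2 -0.53, adjusted p = 0.000935). Traf3, which restrains noncanonical NF-kappaB signalling, rose by 0.68 on the log2 scale. In RANK and costimulatory signalling 2 of 26 genes rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.922); Traf2 (log2 0.66) and the kinase Map3k14 (0.67) rose, and the M-CSF receptor Csf1r (-0.51) and Trem2 (-0.51) fell.

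**Figure D2:**
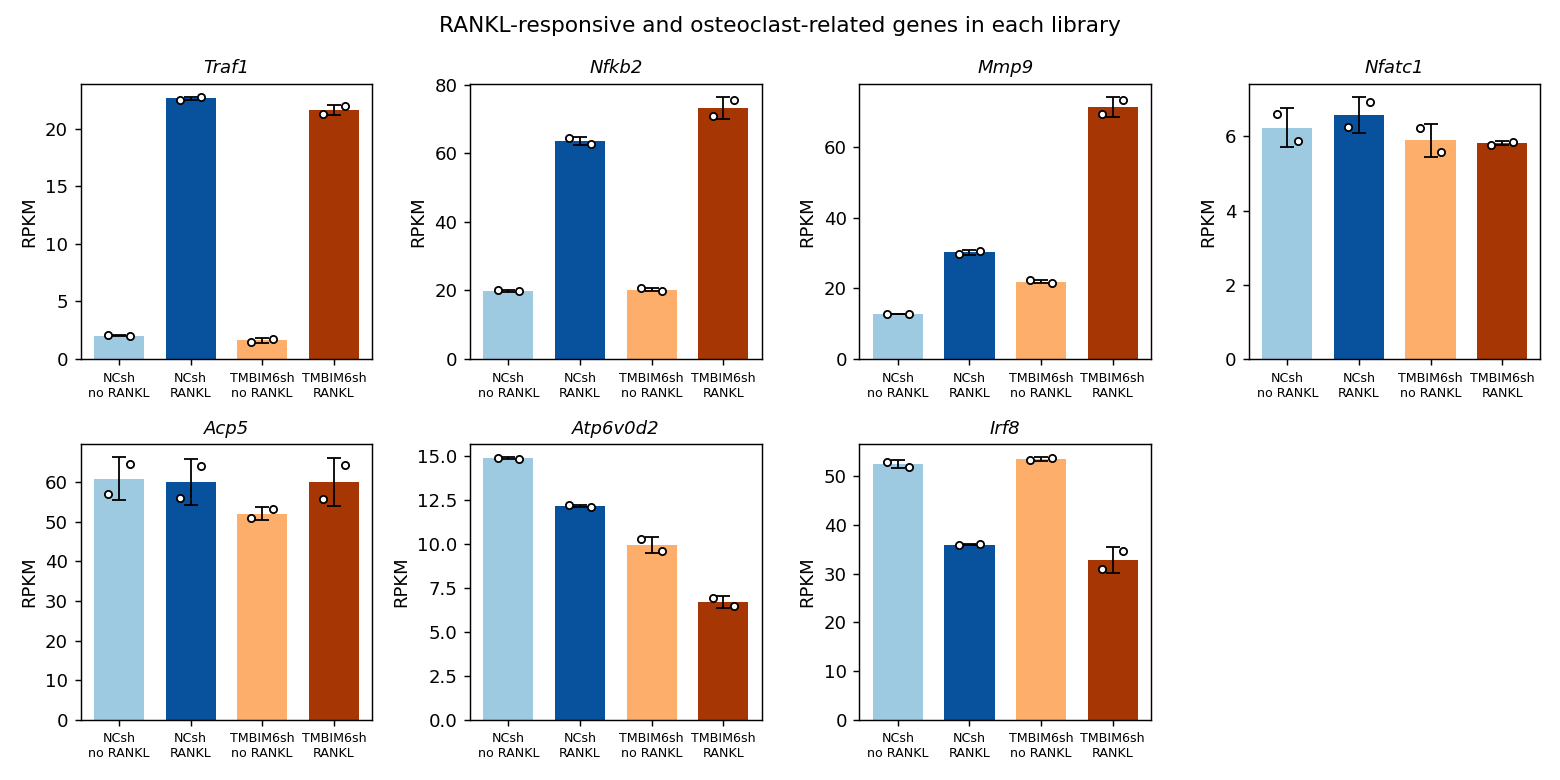
Levels in RPKM (y axes, linear from 0) of 7 genes in the 4 groups; bars are means, lines the SD, and open circles the 2 libraries of each group. Traf1 is at 22.6 and 21.6 RPKM with RANKL against 2.02 and 1.62 RPKM without, while Nfatc1 lies between 5.81 and 6.58 RPKM in all 4 group means.

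Cell division genes moved together under RANKL in NCsh libraries. Of the 30 members of the DNA replication and cell division list 29 rose and 0 fell, 29 also adjusted over the list alone, with a median log2 of 0.66 (adjusted p = 3.00e-21). This call held with an estimated correlation (adjusted p = 0.0262). Top2a, the topoisomerase of dividing cells, rose from 16.9 ± 1.57 to 36.6 ± 1.82 RPKM (SD, n = 2, log2 1.07), and Rrm2, which makes deoxyribonucleotides, from 19.3 ± 0.366 to 37.2 ± 1.5 RPKM (SD, n = 2, log2 0.91). Macrophage markers fell: 11 of 18 were lower and 0 higher, 13 lower adjusted over the list alone, with a median of -0.35 (adjusted p = 4.72e-11; adjusted p = 0.734 with an estimated correlation). Among them were Fcgr3, an immunoglobulin receptor, from 101 ± 8.61 to 64.0 ± 0.48 RPKM (SD, n = 2, log2 -0.65), the mannose receptor Mrc1 (-0.55) and the scavenger receptor Cd36 (-0.44). Interferon-stimulated genes rose, 8 of 31 higher and 0 lower (12 higher adjusted over the list alone, adjusted p = 0.0128, and adjusted p = 0.734 with an estimated correlation), with Ifit1 (0.67) beside Cxcl10. The interferon call ended without NCsh library 2 of the group without RANKL (adjusted p = 0.228) and without NCsh RANKL library 1 (adjusted p = 0.0812).

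Smaller downward shifts in NCsh libraries passed for 5 more lists, and each was lost with an estimated correlation. Lysosomal enzymes and membrane proteins had 3 of 26 lower (adjusted p = 1.54e-04; 0.734 as the adjusted p with an estimated correlation), among them the protease Lgmn (log2 -0.45) and the hydrolase Hexa (-0.25). NRF2 targets and antioxidant enzymes had 5 of 28 lower and 1 higher (adjusted p = 0.0029; adjusted p = 0.734 with an estimated correlation), led by the heme-degrading Hmox1 (-0.47) and the glutathione enzyme Gclm (-0.26). Ribosomal proteins had 0 of 30 called and a median of -0.07 (adjusted p = 0.0029; adjusted p = 0.851 with an estimated correlation). V-ATPase subunits, which acidify lysosomes, had 1 of 15 lower, Atp6v0a1 (log2 -0.48; list adjusted p = 0.0249; adjusted p = 0.734 with an estimated correlation). The TMBIM and BCL-2 families had 2 of 17 lower and 1 higher (adjusted p = 0.0386; adjusted p = 0.734 with an estimated correlation): Bcl2l1 (-0.35) and Tmbim1 (-0.21) fell and Pmaip1 (0.45) rose. Adjusted over each list alone the counts were 3 lower, 5 lower and 1 higher, 0, 1 lower, and 3 lower and 1 higher. Without NCsh library 2 of the group without RANKL, the medians of the ribosomal proteins and the V-ATPase subunits turned to 0.0665 and 0.0119, and the NRF2 and TMBIM calls ended (adjusted p = 0.067 and 0.108). The TMBIM call also ended without NCsh RANKL library 2 (adjusted p = 0.0939).

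Across all 11040 genes tested, RANKL changed 1653 in NCsh libraries, 1214 higher and 439 lower; 43 rose and 10 fell by at least 2-fold. After median-ratio scaling of the libraries the split was 806 higher and 827 lower, and the median of all tested genes moved from 0.06 to -0.00159, so the share of rises depends on the scaling. The count was 694 without NCsh RANKL library 1, 887 without NCsh RANKL library 2, and 1020 in a fit of these 4 libraries alone.

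In TMBIM6sh libraries with RANKL, Traf1 rose from 1.62 ± 0.197 to 21.6 ± 0.466 RPKM (SD, n = 2, log2 3.11, adjusted p = 7.37e-08) and C3 from 8.28 ± 0.53 to 55.8 ± 0.776 RPKM (SD, n = 2, log2 2.62, adjusted p = 7.37e-08). Htra1 (log2 2.75), Cxcl10 (2.29), Gpr132 (2.05), Il2rg (1.95), Nfkb2 (1.80) and Pde2a, a cyclic nucleotide phosphodiesterase (1.74), completed the largest rises. Mmp9 rose from 21.9 ± 0.451 to 71.4 ± 2.82 RPKM (SD, n = 2, log2 1.66, adjusted p = 5.02e-07). The largest falls were those of Rnase4 (log2 -1.60), Ctla2b (-1.58), the microRNA gene Mir1668 (-1.40), Ang (-1.24), Ch25h, which makes an oxysterol (-1.18), the co-receptor Nrp1 (-1.16), Ccnd2 (-1.16) and the plasminogen activator Plau (-1.16). Mir1668 is short, on chromosome 8 at 83723878 to 83723984, so its 7.27 ± 0.48 and 2.21 ± 1.03 RPKM (SD, n = 2) rest on few tags. Its log2 value ran from -1.74 to -1.07 when 1 library was left out.

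Nfatc1 had 5.90 ± 0.446 RPKM without and 5.81 ± 0.0544 RPKM with RANKL in TMBIM6sh libraries (SD, n = 2, adjusted p = 0.939), and Acp5 had 52.1 ± 1.61 and 60.1 ± 6.07 RPKM (SD, n = 2, adjusted p = 0.193). Atp6v0d2 fell from 9.92 ± 0.467 to 6.71 ± 0.332 RPKM (SD, n = 2, adjusted p = 0.00121), and Irf8 had a log2 change of -0.69 (adjusted p = 0.000137). Of 13 osteoclast effectors 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.665, and adjusted p = 0.018 with fry). Osteoclast transcription factors had 7 of 18 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.00492; adjusted p = 0.705 with an estimated correlation), with Fos (log2 0.77), Myc (0.79) and Junb (0.59) among them. Repressors of osteoclast differentiation had 3 of 15 higher and 6 lower (3 and 7 adjusted over the list alone, adjusted p = 0.306), and RANK and costimulatory signalling 2 of 26 higher and 3 lower, the same counts adjusted over the list alone (adjusted p = 0.897).

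Of the cell division list 29 of 30 members rose and 1 fell under RANKL in TMBIM6sh libraries, also adjusted over the list alone, with a median of 0.80 (adjusted p = 1.23e-25; adjusted p = 0.0182 with an estimated correlation). Birc5 (log2 1.20), Top2a (1.08), Rrm2 (1.03) and the helicase subunit Mcm7 (1.01) rose. Macrophage markers had 9 of 18 lower and 0 higher (10 and 1 adjusted over the list alone, adjusted p = 4.47e-07; adjusted p = 0.705 with an estimated correlation), with Fcgr3 (-0.92), the efferocytosis receptor Mertk (-0.81) and Mrc1 (-0.78). Lysosomal genes had 6 of 26 lower (7 adjusted over the list alone, adjusted p = 7.49e-04; adjusted p = 0.705 with an estimated correlation), and interferon-stimulated genes 7 of 31 higher (12 adjusted over the list alone, adjusted p = 0.0137; adjusted p = 0.705 with an estimated correlation). Without TMBIM6sh library 1 of the group without RANKL the interferon list had an adjusted p of 0.0665. Over all genes 1703 changed, 942 higher and 761 lower (919 and 972 after median-ratio scaling), and 61 rose and 27 fell by at least 2-fold. The count was 880 and 826 without TMBIM6sh library 1 or 2 of the group without RANKL, and 996 and 1066 without library 1 or 2 of the group with RANKL.

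The RANKL responses of the NCsh and TMBIM6sh libraries, which share no library, overlapped. In both, 682 genes rose, where 103.6 would if the calls were independent, and 345 fell, where 30.3 would. Another 3 went opposite ways. Both comparisons use 1 spread per gene from all 8 libraries, so the calls are not fully independent. Across genes, which are not independent replicates, the log2 responses had a Pearson r of 0.697 and a Spearman rho of 0.623.

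Without RANKL, the chaperone and cell division lists were lower in TMBIM6sh than in NCsh libraries with the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.752 and 0.0566), and both passed with fry (adjusted p = 0.0092 and 1.43e-04). Cx3cr1, the fractalkine receptor, on chromosome 9 at 120048683 to 120068296, was at 5.80 ± 0.408 RPKM in NCsh and 32 ± 0.274 RPKM in TMBIM6sh libraries (SD, n = 2, log2 2.28, SE 0.0798, adjusted p = 5.32e-07). Slc40a1, the iron exporter ferroportin, was at 15.7 ± 0.147 and 70.7 ± 2.95 RPKM (SD, n = 2, log2 2.10, adjusted p = 4.45e-07), and Laptm5, a lysosomal membrane protein of blood cells, at 118 ± 7.99 and 460 ± 20.8 RPKM (SD, n = 2, adjusted p = 3.44e-06). The chemokine Ccl5 (1.60), Fgl2 (1.52), Gpr31b (1.45), Ch25h (1.42) and the kinase Camk1d (1.32) were the next largest. Apart from Tmbim6, the largest falls were Tusc2 on chromosome 9 at 107563255 to 107566108, from 24.3 ± 0.8 to 4.93 ± 0.161 RPKM (SD, n = 2, log2 -2.09, adjusted p = 7.46e-07), the metallothionein Mt2 (-1.77), the C-type lectin Clec4n (-1.69), the caveolin Cav2 (-1.69), the matrix protein Tgfbi (-1.68), the circadian factor Dbp (-1.64) and Scoc (-1.60).

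Chaperones of the endoplasmic reticulum were lower in TMBIM6sh libraries without RANKL. In the list of the unfolded protein response, chaperones and ERAD 10 of 22 genes fell and 0 rose, also adjusted over the list alone (median -0.20, adjusted p = 1.41e-05; adjusted p = 0.752 with an estimated correlation). Pdia6, a disulfide isomerase, fell from 48.1 ± 1.85 to 16.9 ± 1.86 RPKM (SD, n = 2, log2 -1.46, adjusted p = 9.41e-06), and Hspa5, the chaperone BiP, from 131 ± 5.35 to 74.1 ± 0.605 RPKM (SD, n = 2, log2 -0.82, adjusted p = 6.28e-05). The chaperone Calr (-0.68) and the stress sensor Atf6 (-0.76) fell too. The cell division list had 26 of 30 lower and 0 higher (27 lower adjusted over the list alone; median -0.61, adjusted p = 3.15e-14; adjusted p = 0.0566 with an estimated correlation), with the cyclin Ccnb2 (-1.25), Ube2c (-1.06), Cdc20 (-1.01) and Tk1 (-0.83). Interferon-stimulated genes had 8 of 31 lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.00421; adjusted p = 0.752 with an estimated correlation), among them Gbp2 (-0.79) and Trim30a (-0.71). Without NCsh library 1 of the group without RANKL the interferon list had an adjusted p of 0.0683.

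Lists tied to TMBIM6 or to osteoclasts that did not pass as lists with camera still held changed members without RANKL. Of all 11040 genes tested 24.2% were called in this comparison, so called members alone do not set a list apart from other genes. In the integrated stress response 7 of 19 fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.315), with Ddit3, also called CHOP, at -0.78 and the serine synthesis enzyme Psat1 at 0.93. In calcium handling and calcineurin 5 of 26 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.315), led by the calcineurin subunit Ppp3ca (0.83). With fry the adjusted p was 0.0376. With RANKL 5 were higher and 5 lower (adjusted p = 0.619, and adjusted p = 0.713 with fry). In the TMBIM and BCL-2 families 3 of 17 rose and 4 fell (3 and 6 adjusted over the list alone, adjusted p = 0.434), with the TMBIM member Grina at 0.87 and Tmbim4 at -0.57. V-ATPase subunits had 4 of 15 lower, also adjusted over the list alone (adjusted p = 0.0898, and adjusted p = 0.0376 with fry), with Atp6v1a at -0.90 and Atp6v1g1 at -0.88. Osteoclast effectors had 1 of 13 higher, Mmp9 at 0.74, and 3 lower, with Atp6v0d2 at -0.54 and the integrin Itgav at -0.44 (the same counts adjusted over the list alone, adjusted p = 0.832). Osteoclast transcription factors had 5 of 18 higher (also adjusted over the list alone, adjusted p = 0.315), and repressors 3 of 15 higher and 1, Klf2 at -1.05, lower (also adjusted over the list alone, adjusted p = 0.65). In RANK and costimulatory signalling 4 of 26 rose and 4 fell (4 and 5 adjusted over the list alone, adjusted p = 0.832), with the kinase Mapk14 at -0.47. Over all genes 2673 differed, 1147 higher and 1526 lower in TMBIM6sh libraries, 30 and 55 of them by at least 2-fold; without TMBIM6sh library 1 or 2 of this comparison 1401 and 1396 did.

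With RANKL present, the same hairpin difference was measured in separate libraries. Fgl2, a secreted fibrinogen-like protein, was at 12 ± 0.165 RPKM in NCsh and 61.2 ± 0.243 RPKM in TMBIM6sh libraries (SD, n = 2, log2 2.26, SE 0.0643, adjusted p = 1.11e-07), and Cx3cr1 at 6.43 ± 0.605 and 29.4 ± 1.36 RPKM (SD, n = 2, log2 2.04, adjusted p = 1.05e-06). Laptm5 (1.97), Gpr31b (1.72), Slc40a1 (1.69), Raver2 (1.60), Ccl5 (1.36) and Camk1d (1.35) were higher too. Mmp9 was at 30.2 ± 0.684 and 71.4 ± 2.82 RPKM (SD, n = 2, log2 1.22, adjusted p = 3.45e-06). After Tmbim6 the largest falls were Cav2, on chromosome 6 at 17281185 to 17289130, from 53 ± 3.17 to 13.3 ± 1.36 RPKM (SD, n = 2, log2 -1.92, adjusted p = 1.05e-06), Tusc2 (-1.84), Clec4n (-1.84), Mt2 (-1.78), Scoc (-1.70), the membrane protein Emp1 (-1.66) and the sialic acid receptor Cd33 (-1.64).

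Nfatc1 and Acp5 did not differ past the threshold between hairpins with RANKL (log2 -0.15, adjusted p = 0.239, and log2 0.00081, adjusted p = 0.997). Atp6v0d2 was lower, at 12.2 ± 0.0686 and 6.71 ± 0.332 RPKM (SD, n = 2, log2 -0.77, adjusted p = 7.04e-05). The member counts that follow stand beside a share of 28.6% called among all 11040 genes tested. Osteoclast effectors had 2 of 13 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.851), osteoclast transcription factors 5 of 18 higher and 2 lower (also adjusted over the list alone, adjusted p = 0.111), repressors 2 of 15 higher and 3 lower (also adjusted over the list alone, adjusted p = 0.878), and RANK and costimulatory signalling 3 of 26 higher and 4 lower (4 and 4 adjusted over the list alone, adjusted p = 0.758). The repressor Klf2 (-0.98) and the kinases Mapk14 (-0.60) and Tec (-0.47) were lower, and the transcription factor Prdm1, which represses anti-osteoclastic genes (0.66), was higher.

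The chaperone list again had more falls than rises with RANKL, 11 of 22 lower and 0 higher (14 lower adjusted over the list alone; median -0.24, adjusted p = 1.38e-04; adjusted p = 0.902 with an estimated correlation), with Pdia6 at -1.43, Hsp90b1 at -0.87, Atf6 at -0.80 and Hspa5 at -0.61. Cell division genes had 24 of 30 lower and 0 higher (24 and 1 adjusted over the list alone; median -0.57, adjusted p = 5.58e-09; adjusted p = 0.133 with an estimated correlation), with Bub1b at -1.02, Plk1 at -0.97 and Ccnb2 at -0.93. Interferon-stimulated genes had 15 of 31 lower and 1 higher, also adjusted over the list alone (median -0.26, adjusted p = 0.0194; adjusted p = 0.971 with an estimated correlation), with Trim30a at -0.86 and Rsad2 at -0.81. Ribosomal proteins passed upward with a median of 0.10 (adjusted p = 0.0222; adjusted p = 0.971 with an estimated correlation), although 0 of 30 members rose and 1, Rpl5 at -0.63, fell, also adjusted over the list alone. The interferon and ribosomal calls ended without NCsh RANKL library 1 (adjusted p = 0.148 and 0.184) or without TMBIM6sh RANKL library 2 (adjusted p = 0.087 and 0.184).

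Over all genes 3157 differed with RANKL, 986 higher and 2171 lower in TMBIM6sh libraries; 24 and 96 did so by at least 2-fold. Median-ratio scaling gave 1559 higher and 1693 lower and moved the median of all tested genes from -0.07 to -0.00778. The count was 1870 and 2077 without NCsh RANKL library 1 or 2 and 2071 without TMBIM6sh RANKL library 1. Between the 2 RANKL states 724 genes were higher in both, where 102.4 would be if the calls were independent. Lower in both were 1218, where 300.1 would be, and 4 went opposite ways. These calls too share 1 spread per gene and are not fully independent. Across genes, which are not independent replicates, Pearson's r between the states was 0.775 and Spearman's rho 0.736.

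**Figure D3:**
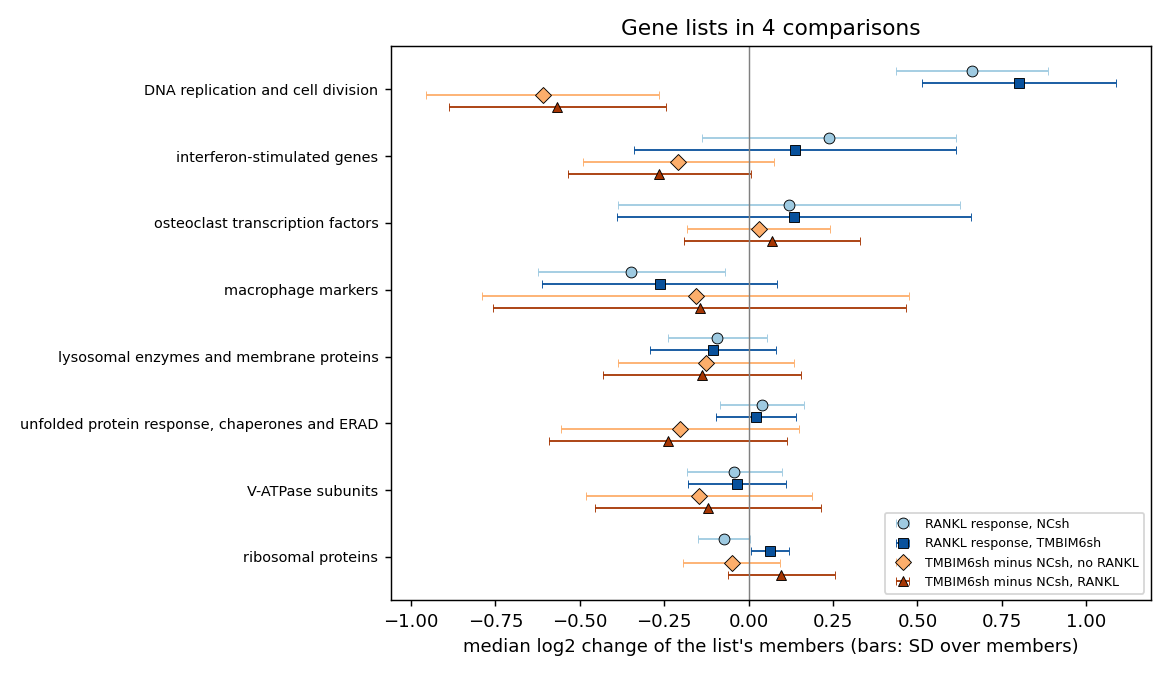
Median log2 change of the tested members (x axis) of 8 gene lists (y axis) in 4 comparisons; symbols are medians and lines the SD over members. Cell division genes lie at 0.66 and 0.80 for the RANKL responses and at -0.61 and -0.57 for TMBIM6sh minus NCsh.

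The changed genes differed in short words of their 3' untranslated regions (UTRs), the part of a messenger RNA that small RNAs bind. Among 10261 genes with a searched 3' UTR, the 5 words most associated with lower levels in TMBIM6sh libraries without RANKL were CTATGAA, TCTATGA, CTATGAT, TATGATA and ATGATAA, and with RANKL, in libraries not used to pick the words, 46.6% of the 2065 searched genes that were lower carried at least 1 of them, against 24.9% of the others. The 5 words most associated with higher levels were ACTGCAA, CACTGCA, TACTGCA, AACTGCA and ACTGCAC, carried by 61.2% of the 948 searched genes higher with RANKL against 32.2% of the others. Unlike the ranking of the words, these shares were not adjusted for 3' UTR length or GC content. Of the 7 largest falls other than Tmbim6, 4 without RANKL (Tusc2, Clec4n, Cav2 and Scoc) and 6 with RANKL (these with Emp1 and Cd33) carry words of the first set. Of the 8 largest rises, 5 without RANKL (Cx3cr1, Slc40a1, Laptm5, Gpr31b and Camk1d) and 6 with RANKL (these with Raver2) carry words of the second set. The counts without RANKL reuse the libraries that picked the words. Emp1 and Cd33, which fell, and Slc40a1, Laptm5 and Camk1d, which rose, carry words of both sets, and Fgl2, the largest rise with RANKL on the log2(RPKM + 1) scale, carries words of the first set only. Mt2, Tgfbi and Dbp among the falls and Ccl5 and Ch25h among the rises carry neither. Among the chaperone genes Pdia6, Calr and Atf6 carry words of the first set and Hspa5 does not. The 6 chaperone-list members with such words had a median of -0.69 with RANKL and the others -0.19. For V-ATPase subunits the medians were -0.65 in the 5 members with words of the first set and -0.12 in the others, and for cell division genes -0.44 in the 6 members with words and -0.62 in the others. In calcium handling and calcineurin 10 of 26 members, Ppp3ca among them, carry words of the second set. With RANKL 5 of these were called higher and 0 of the others, with medians of 0.20 and -0.13. Without RANKL the counts were also 5 and 0.

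**Figure D4:**
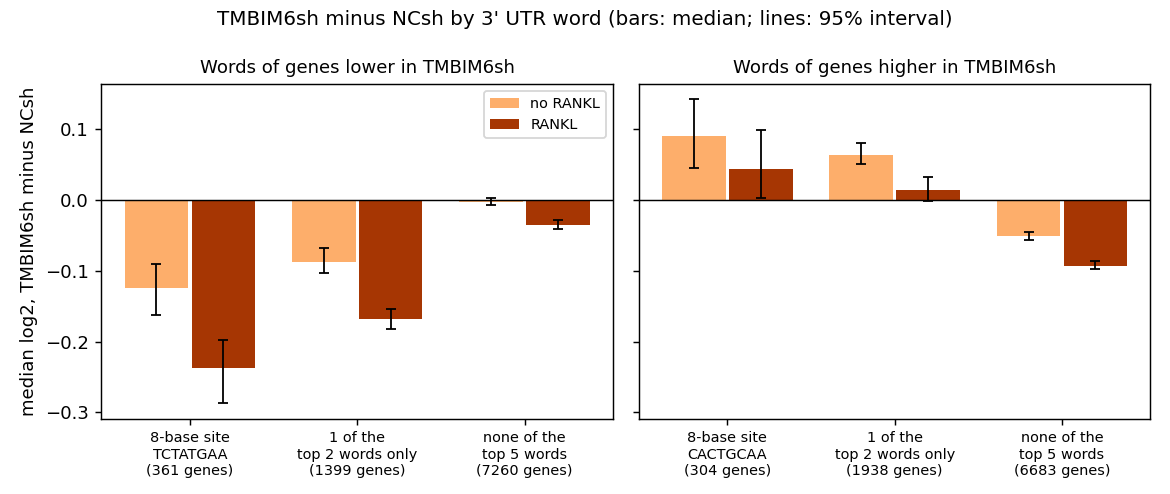
Median log2 difference of TMBIM6sh minus NCsh (y axis) for genes grouped by 3' UTR words of the first set (left) and second set (right), without and with RANKL; bars are medians over genes and lines 95% intervals of the median. With RANKL, 361 genes with TCTATGAA lie at -0.24, and 7260 genes with none of the 5 words at -0.03. The words were picked in the libraries without RANKL. The middle class of each panel holds genes with 1 or both of the top 2 words but not the 8-base site. The medians were not adjusted for 3' UTR length or GC content.

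Whether the RANKL response differed between NCsh and TMBIM6sh libraries was tested as an interaction. A single gene of 11040 passed, the small nucleolar RNA Snord104 on chromosome 11 at 106500991 to 106501063 (log2 -2.88, SE 0.259, adjusted p = 0.00998), from 1 to 10 tags per library. Fgl2 came next with 0.74 (SE 0.0909, adjusted p = 0.0725), then the microRNA gene Mir1893 with 1.14 (adjusted p = 0.113), Mmp9 with 0.48 (SE 0.0842, adjusted p = 0.51), Snord83b with 1.47 and Mir3074-1 with 1.11 (adjusted p = 0.51 each). Downward, Fam8a1 (-0.76), Ints6l (-0.58), Pet117 (-0.51) and Snora20 (-1.16) had the next smallest p (adjusted p = 0.51 each). Adjusted over the list alone, 1 of the 13 osteoclast effectors passed upward, Mmp9. The interaction was 0.22 for Acp5 (adjusted p = 0.701) and -0.08 for Nfatc1 (adjusted p = 0.883).

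Ribosomal proteins (median 0.14, adjusted p = 6.48e-08), cell division genes (median 0.11, adjusted p = 1.03e-04) and oxidative phosphorylation genes (median 0.08, adjusted p = 1.79e-04) passed upward in the interaction with 0 members called in each, also adjusted over each list alone. With an estimated correlation none of these 3 lists passed (adjusted p = 0.957, 0.451 and 0.957), nor did any with fry (adjusted p = 0.911, 0.426 and 0.911). Without NCsh library 2 of the group without RANKL the ribosomal median was -0.0175 and that of oxidative phosphorylation -0.0264. The Snord104 call ended without filter (adjusted p = 0.113), without TMBIM6sh library 1 of the group without RANKL (adjusted p = 0.0937) and without TMBIM6sh RANKL library 1 or 2 (adjusted p = 0.188 and 0.184). In the interaction 857 genes had an unadjusted p under 0.05, where 552 would by chance, but the count was 525 without TMBIM6sh library 2 and 1418 without NCsh library 1 of the groups without RANKL, and 566 without NCsh RANKL library 1.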

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

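Of the tests in this part voom and the scaling without Rn45s and Lars2 were chosen only after the result was seen. The entries below come from the test of the difference between the RANKL responses of TMBIM6sh and NCsh libraries. A single gene, a count of 1, passed that test of 11040, and 857 had an unadjusted p under 0.05 (525 without TMBIM6sh replicate 2 and 1418 without NCsh replicate 1 of the groups without RANKL, 566 without NCsh RANKL replicate 1, and 552 by chance). Voom on the recovered tags, chosen after seeing the data, also gave 1 gene: it called the Fgl2 interaction (adjusted p = 0.00793) and not that of Snord104.

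Snord104, a small nucleolar RNA of 72 bases, had an interaction of -2.88 on the log2 scale. The Snord104 interaction rests on 1 and 2 tags in NCsh libraries without RANKL, 10 and 7 with RANKL, 8 and 8 in TMBIM6sh libraries without RANKL, and 2 and 2 with RANKL. Over the alternatives its adjusted p ran from 0.00392 to 0.335, and with a pseudocount of 0.1 the value was -4.22, so the size depends on the pseudocount at these tag numbers. No explanation was tested for it.

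The cell division list differed between the hairpins' RANKL responses with a median of 0.11 (adjusted p = 1.03e-04; adjusted p = 0.451 with an estimated correlation), with 0 of 30 members called. No explanation was tested for it.

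Ribosomal proteins (median 0.14) and oxidative phosphorylation genes (median 0.0822) were higher in the interaction with the preset correlation, with 0 members called in each, and neither passed with an estimated correlation (adjusted p = 0.957 for each). A cause in 1 library was tested by leaving each out. Without NCsh library 2 of the group without RANKL the ribosomal median was -0.0175, and the median of all tested genes in that fit was -0.0588. Without library 1 of the same group the ribosomal median was 0.299. The ribosomal genes of NCsh library 2 without RANKL lay 0.184 above the mean of the 8 libraries while its duplicate lay at -0.119. TMBIM6sh RANKL library 2 lay at 0.121 and its duplicate at -0.00736, which also raises the interaction. A trend with transcript length and GC content was tested too, since the median exon length is 738 bases for ribosomal and 1171 for oxidative phosphorylation genes against 2651 for all: removing it left 0.0529 (SD over members 0.0646) and 0.0187 (SD 0.0813), or shares of 0.385 and 0.228 of the medians. The test required both medians within 0.03 of 0, which oxidative phosphorylation met and ribosomal proteins did not. The size and sign of the pattern thus depend on single libraries. With 2 libraries in a group, leaving 1 out cannot show which of the pair is off. Whether length and GC explain it as well cannot be told apart here, and a biological difference between the hairpins stays open, as untested.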

How the results depend on the processing

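Voom and the scaling without Rn45s and Lars2 were tests chosen only after the data were seen. Tmbim6 kept its direction and call in 32 of 32 alternative values; called named genes did in 1187 of 1199 and lost the call in 12, and called lists did in 364 of 381, lost the call in 13 and reversed in 4 over these refits at the preset correlation. With an estimated correlation 22 of the 24 called lists lost their call, and 2 kept it, cell division under RANKL in NCsh (adjusted p = 0.0262) and in TMBIM6sh libraries (adjusted p = 0.0182). These losses cannot be put down to correlation between members alone. For TMBIM6sh minus NCsh without RANKL the estimated correlation of cell division was 0.026, and its call still ended (adjusted p = 0.0566). With RANKL, fry passed cell division (adjusted p = 2.81e-04), chaperones (0.0064) and interferon-stimulated genes (0.0428) between hairpins, but not ribosomal proteins (0.748). There fry also passed V-ATPase subunits and markers of MHC class II and dendritic cells (adjusted p = 0.0428 each). Camera called neither (adjusted p = 0.152 and 0.403). In both RANKL responses cell division, macrophage markers and osteoclast transcription factors also passed with fry (adjusted p of at most 0.0343). The other lists called there did not (adjusted p of 0.05086 or more). With a replicate block the counts were 1608, 1670, 2654, 3128 and 1. The count for RANKL in NCsh libraries was 1020 with only the 4 libraries of the comparison and 2484 with voom, and ran from 694 (without NCsh RANKL replicate 1; 887 without replicate 2) to 1520 when 1 library was left out. The count for RANKL in TMBIM6sh libraries ran from 826 to 2056 (826 and 880 without TMBIM6sh replicate 2 or 1 without RANKL, 996 and 1066 without replicate 1 or 2 with RANKL), that for TMBIM6sh minus NCsh without RANKL from 1396 to 2523 (1396 and 1401 without TMBIM6sh replicate 2 or 1), and that with RANKL from 1870 to 3558 (1870 and 2077 without NCsh replicate 1 or 2, 2071 without TMBIM6sh replicate 1). The interaction count was 8 with no filter, 2 with no intensity trend, and 0 to 2 when 1 library was left out (0 without TMBIM6sh replicate 1 without RANKL or either TMBIM6sh replicate with RANKL). Leaving out 1 library, the interaction median of oxidative phosphorylation ran from -0.0264 to 0.21 and that of ribosomal proteins from -0.0175 to 0.299, and in the RANKL response of NCsh libraries the ribosomal median ran from -0.213 to 0.0665 and that of the V-ATPase from -0.0894 to 0.0119; each of these 4 reversed without NCsh replicate 2 without RANKL. Fewer libraries leave fewer degrees of freedom; beyond that the cause was not tested. Genes at a few tags per library, such as Snord104, are at the limit of this depth.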

Other observations

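The tests of scaling, of site type, of the share of genes with a word, and every test of the higher genes were chosen only after the result was seen; the first test of words in the 3' UTR was set out before. For TMBIM6sh minus NCsh with RANKL, where 28.6% of all tested genes were called, these lists did not pass. Autophagy genes had 6 of 25 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.851; median and mean below 0, test upward), with the autophagosome protein Map1lc3a at -0.66. Cholesterol synthesis had 8 of 21 higher and 3 lower (8 and 4 adjusted over the list alone; adjusted p = 0.0771), with the synthase Hmgcs1 at 0.38. Glycolysis had 2 of 18 higher and 4 lower (3 and 4 adjusted over the list alone; adjusted p = 0.878), p53 targets 5 of 16 higher and 3 lower (the same adjusted over the list alone; adjusted p = 0.338) with Trp53inp1 at -1.22, and NRF2 targets 5 of 28 higher and 11 lower (5 and 13 adjusted over the list alone; adjusted p = 0.851) with Hmox1 at 0.92 and the ferritin chain Fth1 at 1.07. Inflammatory cytokines had 3 of 17 higher and 2 lower (the same adjusted over the list alone; adjusted p = 0.643), with Ccl5 at 1.36 and the receptor antagonist Il1rn at -0.43. NADPH oxidase had 0 of 8 higher and 1 lower, Rac1 at -0.24 (the same adjusted over the list alone; adjusted p = 0.958).

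Marker lists of other cells were low in these libraries. Of 18 markers of MHC class II and dendritic cells 8 were tested and 2 were lower, H2-DMa at -0.58 and Itgax at -0.26 (also adjusted over the list alone). The list had an adjusted p of 0.403, and of 0.0428 with fry. Of 17 stromal and osteoblast markers 6 were tested and 0 passed (adjusted p = 0.631). Of 16 neutrophil markers 3 were tested, with S100a8 at -0.85 and Lcn2 at 0.54, of 16 lymphocyte markers 2, with Cd79b at -0.71, and of 16 erythroid, mast cell and basophil markers 0. Those not tested reached at most 0.509, 0.343 and 0.27 RPKM in any library.

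Of the genes lower in TMBIM6sh libraries in both RANKL states, median-ratio scaling left 1057 of 1218, or 86.8%, lower in both. This argues against scaling as the whole cause. Of the searched ones 51.7% (SE 1.46) carry 1 of the top 5 words, so matches to these words in the searched 3' UTRs do not reach every lower gene. Seed matches through other words or outside the 3' UTR were not counted and stay open. Off-target silencing by the hairpin's seed was to put a word of the Tmbim6 transcript first; TCTATGA ranked second in both states (z -12.9 with RANKL, most extreme permutation -4.94), behind CTATGAA, which Tmbim6 lacks and which shares 6 of its bases, so the test as written was not met. Carriers of TCTATGA were 12.5 percentage points more frequent among these genes, and 10.2 among genes lower with RANKL, in libraries not used to pick the word. Of the 5 lower words 4 (TCTATGA, CTATGAT, TATGATA and ATGATAA) occur in Tmbim6 and join to TCTATGATAA, found once, in exon 10 outside the coding sequence, while 20.9% of all words tested occur in that transcript, as do CACTGCA, TACTGCA and ACTGCAC of the words of higher genes. With RANKL, carriers of TCTATGAA lay -0.20 on the log2 scale from genes with none of the words. The medians were -0.24 for the 8-base site, -0.17 for 1 or both of the top 2 words without it, and -0.03 for none. These medians and the shares of carriers were not adjusted for 3' UTR length or GC content. An effect of length can therefore not be separated from the grading by site.

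These values are consistent with seed-matched silencing in part of the lower genes (-0.20 between site and no site), as a hypothesis; the hairpin's sequence was not used here, an endogenous small RNA was not tested, and loss of TMBIM6 stays open, untested.

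Genes higher in TMBIM6sh libraries in both states form the second pattern. Carriers of ACTGCAA, CACTGCA, TACTGCA, AACTGCA or ACTGCAC were 29.0 percentage points more frequent among genes higher with RANKL, in libraries not used to pick the words, than among other genes, and z for ACTGCAA was 16.2 without and 15.5 with RANKL (most extreme permutations 4.72 and 5.27). With RANKL the medians were 0.04 for genes with CACTGCAA (95% interval 0.0029 to 0.099) and -0.09 for none. Genes with 1 or both of the top 2 words but not CACTGCAA had a median of 0.01 (-0.0016 to 0.032), and this interval overlaps that of CACTGCAA. Here too the medians and shares were not adjusted for 3' UTR length or GC content. A candidate explanation is repression through these words that is stronger in the NCsh libraries, such as by the NCsh hairpin or a small RNA that TMBIM6sh lowers; which of these cannot be told apart, and loss of TMBIM6 is untested. Of the searched genes higher in both states 69.8% (SE 1.72) carry 1 of these 5 words, so matches to these words in the searched 3' UTRs do not reach every higher gene. Seed matches through other words or outside the 3' UTR were not counted and stay open.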
